A study of Schizosaccharomyces pombe with 41 samples.

How the data were processed

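The libraries were paired-end sequences of MNase-digested chromatin immunoprecipitates and their inputs, and of H4S48C chemical cleavage, from fission yeast. Per the submitters' processing notes, reads were aligned with Novoalign 2.08. The deposited files hold, per the labels and the values, 1 line per fragment with its chromosome and its first and last position, a kind of unit (other: fragment start and end positions) with no count or normalization by the authors. The genome build, the treatment of reads that map to several places, the handling of duplicates and any length filter are not given in the sources used here. The last positions of the chromosomes were checked against the reference assembly ASM294v3, and coordinates refer to it. A contig named MTR in the files is not part of that reference, and it and the mitochondrial DNA were left out of the comparisons. No raw reads were used here.

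All fragments were kept, repeated ones included, and each was counted at its midpoint. A density is the number of fragments per kb over the median 1-kb window outside the centromeres and 5 kb on either side of them. Central cores, inner repeats and outer repeats were found by aligning each centromere with itself and with the other centromeres in blastn. The annotation of the reference gave the stretches searched and the border tRNA genes. At centromere I the inner repeats so defined reach past the border tRNA genes on both sides. Windows of 1000 bp and gene bodies with a mean of at least 10 fragments were tested on log2 CPM (fragment counts scaled to library size) with a pseudocount of 1, centred on the median window of the same part of the arms. The tool was limma 3.58.1 in R 4.3.3, with a trend in the variance and the robust option off. Calls needed a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The crosslinked contrasts of Cnp1-HA and of Cnp20 with their inputs had MNase time as a block. The contrast of Cnp20 with Cnp1-HA was the interaction of protein with immunoprecipitation over the 12 crosslinked libraries, without a block for time. Runs were read from the dates in the sample titles and taken as sequencing runs, which the labels do not state. Replicate numbers follow these dates in the needle-extracted Cnp1-FLAG libraries of 5 and 10 min, whose differences between replicates had r = 0.264 across windows, and r was 0.0213 and 0.0394 between these and the salt-extracted ones. They were not used to pair libraries in the main tests, and values within replicate blocks are given beside these.

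The 9 gene lists were tRNA, ribosomal protein, 5S rRNA, Tf2 retrotransposon, subtelomeric (within 50 kb of a chromosome end), glycolysis and translation, core histone, meiotic (under facultative heterochromatin) and kinetochore genes. They were tested with camera in limma at a preset correlation of 0.01 and with an estimated correlation. Single values were compared between groups with two-sided exact permutation tests, named with the smallest p each design allows. Profiles within the cores were midpoints in steps of 10 bp, smoothed over 50 bp, and Cnp1-FLAG peaks were at least 300 bp apart. Shares of fragments have 95% Wilson intervals, which cover counting error only, since fragments copied by PCR are not independent molecules. Depth ran from 707128 to 17072536 fragments per library, and distinct fragments made up 6.18% to 99.0% of them. The median arm window held 9 fragments in the shallowest Cnp1-FLAG salt library and in the native Cnp1-HA salt library, which limits their densities.

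The regions named in the text follow a rule: adjacent called windows more than 5 kb from a centromere were merged, and the 15 of highest and the 5 of lowest mean change per contrast that went the same way in every immunoprecipitate are named, with centromere parts, border tRNA genes, the mating-type locus, subtelomeres, strain markers, the kinetochore genes and the 3 highest Cnp1-FLAG peaks per core. Groups, comparisons, tests, gene lists, this rule and most alternatives were fixed before the data were examined. The alternatives were windows of 500 bp, a pseudocount of 5 CPM, no centring, distinct fragments only, fragments of up to 120 bp or above 120 and up to 200 bp, 1 sequencing run only, MNase time as a covariate, genes with 500 bp on either side, smoothing over 150 bp, division of profiles by the input, and leaving out each library in turn. Added after the data were seen were scaling to a trimmed mean window (10% on each side), limma without a trend, leaving out the ribosomal DNA, gene lists in the interaction contrast, H4S48C fragment ends, averages of native extracts per run and time, and distinct fragments or length classes (by mean and by median window) for the ratios beside the centromeres, at the borders and for gene lists.

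The window tests were tested on simulated data with 100 changed windows per fold: 4-fold changes were called in 100% of them in each contrast and 2-fold changes in 49%, 45%, 42% and 35% (Cnp1-FLAG, Cnp1-HA, Cnp20 and the interaction), with 0, 0, 0 and 5 false calls. A 2-fold change lies at the fold threshold itself, so estimates just under it are not called. The simulated centromere windows had the median level, and noise was independent between windows, with no effect of run or MNase time. These settings lack the shift of the median window in the real contrasts, so the false calls give no error rate for them. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and blastn 2.17.0. Single libraries without an input of their own were described and not tested.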

Results

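The series measured where 5 inner kinetochore proteins sit on the 3 regional centromeres of fission yeast, and how histone H4 is placed there. A regional centromere of this yeast holds a central core, inner repeats on both sides of it, tRNA genes at the border and outer repeats beyond them. The proteins were Cnp1 (the centromeric histone H3 variant, CENP-A), Cnp3 (CENP-C), Cnp20 (CENP-T), Mis6 (CENP-I) and Scm3 (the chaperone that loads Cnp1). The 41 libraries comprised 25 immunoprecipitates, 13 inputs and 3 H4S48C libraries, in which histone H4 with a cysteine at position 48 directs chemical cleavage of DNA. Chromatin was digested with MNase for 1 to 20 minutes. It was either native and released through a needle, native and released from the remaining pellet with 150 mM NaCl, or crosslinked with 1% formaldehyde.

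Cnp1-FLAG had 6 immunoprecipitates and 3 inputs from needle extraction, and 4 immunoprecipitates and 1 input from salt extraction. Crosslinked Cnp1-HA and crosslinked Cnp20-FLAG each had 3 immunoprecipitates and 3 inputs. The needle and salt extractions of native Cnp20-FLAG, and native Cnp1-GFP, had 1 immunoprecipitate and 1 input each. The 2 native Cnp1-HA extractions, Cnp3-Myc, Mis6-GFP, Mis6-HA and Scm3-FLAG had 1 immunoprecipitate each and no input of their own among the files. The labels do not say whether replicates came from separate cultures, so replicates may be technical. Depth ran from 3340926 to 9135255 fragments in needle Cnp1-FLAG immunoprecipitates, from 707128 to 3764643 in the salt ones, from 1418507 to 4127487 in crosslinked Cnp1-HA and from 2967080 to 4982269 in crosslinked Cnp20. The single immunoprecipitates held between 1573106 (native Cnp1-HA, salt) and 11838855 fragments (native Cnp20, needle), the inputs between 3171164 and 17072536, and the H4S48C libraries between 6606175 and 8319062.

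The first question was how strongly Cnp1 marks each central core. In needle-extracted Cnp1-FLAG immunoprecipitates, core I (3769078 to 3773195) had a density of 1402 ± 637, core II (1620807 to 1627609) 1278 ± 571 and core III (1097071 to 1101923) 1241 ± 578 (SD, n = 6), where 1 is the median 1-kb window of the chromosome arms. Inner repeats had 877 ± 368 and outer repeats 37.4 ± 10.7. Outer repeats of centromere II had the highest mean of the 3 at 52.8 ± 16.9, against 37.2 at centromere I and 29.2 at centromere III. As defined here, the outer repeats of centromere II take in the border tRNA genes. At centromere I these lie in the inner repeats, and at centromere III mostly so. How far this moves the ranking was not tested. A stretch of 3307 bp of core I has a copy at centromere III (1098933 to 1102240), which reaches from core III into its right inner repeat. Densities there are averages over both copies. In the 3 inputs the cores had 1.17 ± 0.388, the inner repeats 0.993 and the outer repeats 1.70 ± 0.0248. The cores together were 1039-fold denser in immunoprecipitates than in inputs (two-sided exact permutation test on the log2 scale, p = 0.0238, the smallest that 6 against 3 libraries allow). Within the only run that held inputs the fold was 782 (exact p = 0.1, the smallest possible there).

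**Figure D1:**
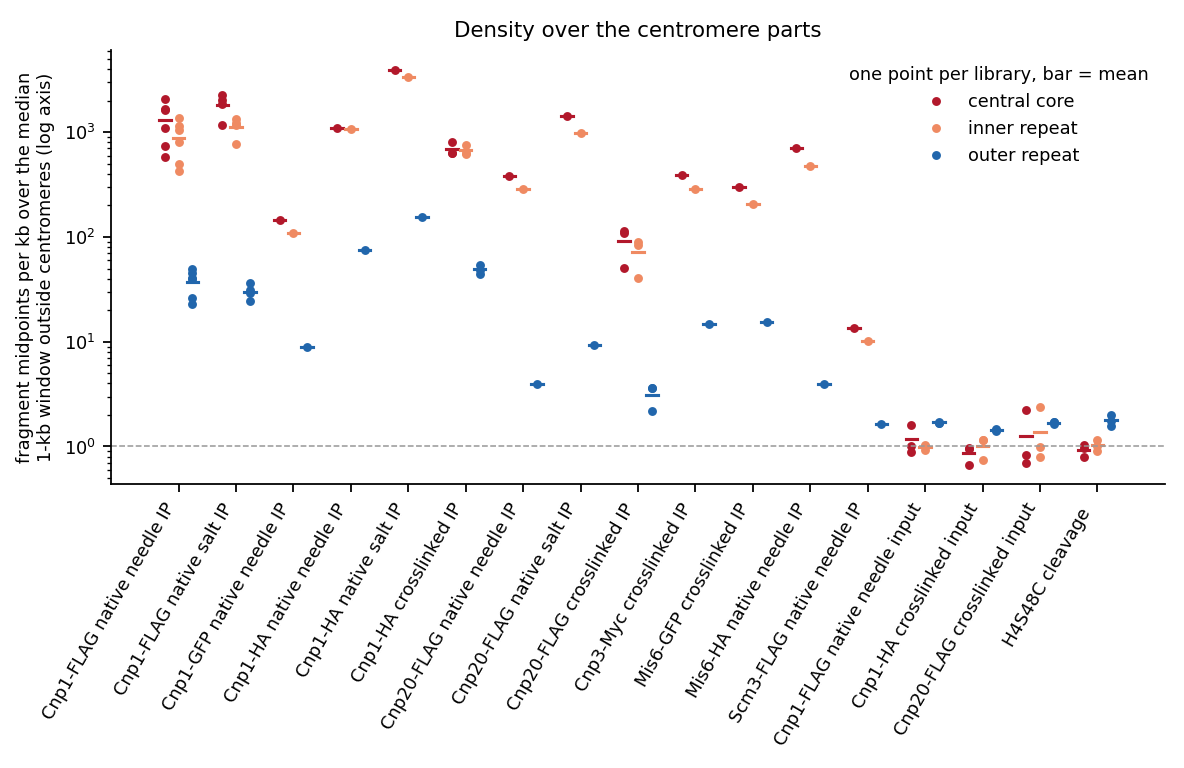
Density of fragments in central cores, inner repeats and outer repeats (log axis, median arm window = 1), with a point per library and a bar for the mean of each group of immunoprecipitates, replicated inputs or H4S48C libraries. Needle-extracted Cnp1-FLAG immunoprecipitates averaged 1299 in the cores and their inputs 1.17.

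Cnp1 at the cores was then compared between extractions and digestion times. Salt extraction left the cores at 1823 ± 465 (SD, n = 4), the inner repeats at 1131 ± 244 and the outer repeats at 30.1 ± 4.8, with 1.71% of the core density over outer repeats against 3.15 ± 0.836% after needle extraction. Over digestion times that both extractions had, the core density after salt was 1.31 times that after needle extraction (1444 ± 527, n = 5), which did not pass the test (two-sided exact permutation p = 0.302, smallest possible 0.0159). Within the run that held both, the ratio was 1.09, from ratios of 1.06, 1.12 and 1.08 at 5, 10 and 20 min. Pairing libraries within replicate blocks gave 1.17 (exact p = 0.5), from ratios of 1.23, between libraries of different runs, and 1.12. Cores had 1650 ± 7.14 after 10 min and 918 ± 263 after 5 min (n = 2 each), a ratio of 1.83 with exact p = 0.333, the smallest that this design allows. The replicate blocks gave 2.25 and 1.5 (exact p = 0.5). Counting each distinct fragment once moved the salt to needle ratio to 2.02 (exact p = 0.0159). The needle libraries held 1027589 to 3450721 fragments in the cores and the salt ones 287400 to 1628836. Whether this difference in depth moves the ratio of distinct fragments was not tested.

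The same question was put to crosslinked Cnp1-HA, with another tag and formaldehyde. Cores I, II and III had 710, 669 and 710, the inner repeats 673 ± 70.6 and the outer repeats 49.2 ± 4.89 (SD, n = 3). The cores together had 692 ± 102 in immunoprecipitates and 0.862 ± 0.168 in inputs, an 809-fold difference (two-sided exact permutation p = 0.1, the smallest for 3 against 3), with all libraries in 1 run. The single native Cnp1-HA libraries had 1095 (needle) and 3941 (salt) over the cores and 1065 and 3342 over inner repeats. The salt library had a median arm window of 9 fragments, so its densities are imprecise.

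Cnp20 was compared with Cnp1 in crosslinked chromatin. Cores I, II and III had 97.3, 87.0 and 92.1 in Cnp20 immunoprecipitates, the inner repeats 71.9 ± 26.9 and the outer repeats 3.13 ± 0.818 (SD, n = 3). The cores together had 91.3 ± 35.5 against 1.25 ± 0.856 in inputs, a 78.7-fold difference (two-sided exact permutation p = 0.1, the smallest possible). Inner repeats had 0.793 ± 0.0199 of the core density in Cnp20 and 0.976 ± 0.0396 in Cnp1-HA. That ratio was 0.813 times as high in Cnp20, with no overlap between the 3 libraries of each (exact p = 0.1, the smallest possible). In needle-extracted Cnp1-FLAG it was 0.687 ± 0.0429 (n = 6), in other runs and without crosslinking. Single native Cnp20 libraries had 382 (needle) and 1433 (salt) over the cores, and the input of the salt extraction had 4.28.

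Cnp3, Mis6, Scm3 and Cnp1-GFP were each seen in single libraries, so their values have no replicate error and were not tested. Cnp3-Myc had 389 over the cores, 287 over inner repeats and 14.9 over outer repeats. Mis6-GFP (crosslinked) had 300.4, 205 and 15.5, and Mis6-HA (native) had 710, 482 and 3.91 in the same order. Cnp1-GFP had 144, 109 and 8.84. Scm3-FLAG had 13.7, 10.2 and 1.63, with 1.56% of its fragments in the cores (95% Wilson interval 1.54 to 1.57). The shares in the cores were 21.1% for Cnp3-Myc, 18.1% for Mis6-GFP and 31.3% for Mis6-HA, against 0.0785% to 0.403% in the 13 inputs. H4S48C libraries had 0.933 ± 0.131 over the cores (SD, n = 3).

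The tRNA genes that border the inner repeats were a further question, since they mark the edge of the core domain. At centromere II these are SPBTRNAILE.06, SPBTRNAALA.09 and SPBTRNAVAL.06 on the left (1618293 to 1619256) and SPBTRNAVAL.07, SPBTRNAALA.10 and SPBTRNAILE.07 on the right (1629159 to 1630122). Over the border clusters of all 3 centromeres, needle-extracted Cnp1-FLAG immunoprecipitates had 907 ± 363 in the 1 kb inside, 129 ± 61.0 over the tRNA genes and 116 ± 41.7 in the 1 kb outside (SD, n = 6). The drop from inside to outside was 7.72 ± 0.899-fold in immunoprecipitates and 0.678 ± 0.0925-fold in inputs (two-sided exact permutation p = 0.0238, the smallest possible). Crosslinked Cnp20 dropped 10.3 ± 0.593-fold and crosslinked Cnp1-HA 5.22 ± 0.155-fold (n = 3 each, exact p = 0.1, the smallest possible). The 2 native Cnp20 libraries dropped 21.1-fold and 25.6-fold. They are the needle and salt extracts of 1 time and run and may come from the same digest, so extracts were averaged per run and time. The drop was then 23.2-fold in Cnp20 (n = 1) and 8.54-fold in native Cnp1-FLAG (6.61 to 10.95, n = 7, in other runs; exact permutation p = 0.125, the smallest possible). Over the tRNA genes themselves native Cnp20 kept 5.59% of its inside density and native Cnp1-FLAG 13.04% (same n, exact permutation p = 0.125), whereas the crosslinked libraries had 28.6 ± 10.5% and 28.5 ± 12.1% (exact p = 1, n = 3 each). Single libraries dropped 25.8-fold (Mis6-HA), 6.0-fold (Mis6-GFP), 6.58-fold (Cnp3-Myc) and 5.23-fold (Scm3-FLAG). These border tests were chosen after the values were seen. With distinct fragments only the drops were smaller (4.36-fold in Cnp1-FLAG, 3.60-fold in Cnp1-HA, 8.33-fold in crosslinked Cnp20, 11.8-fold in native needle Cnp20, 13.04-fold in native salt Cnp20 and 15.4-fold in Mis6-HA). Whether depth moves these drops was not tested.

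**Figure D2:**
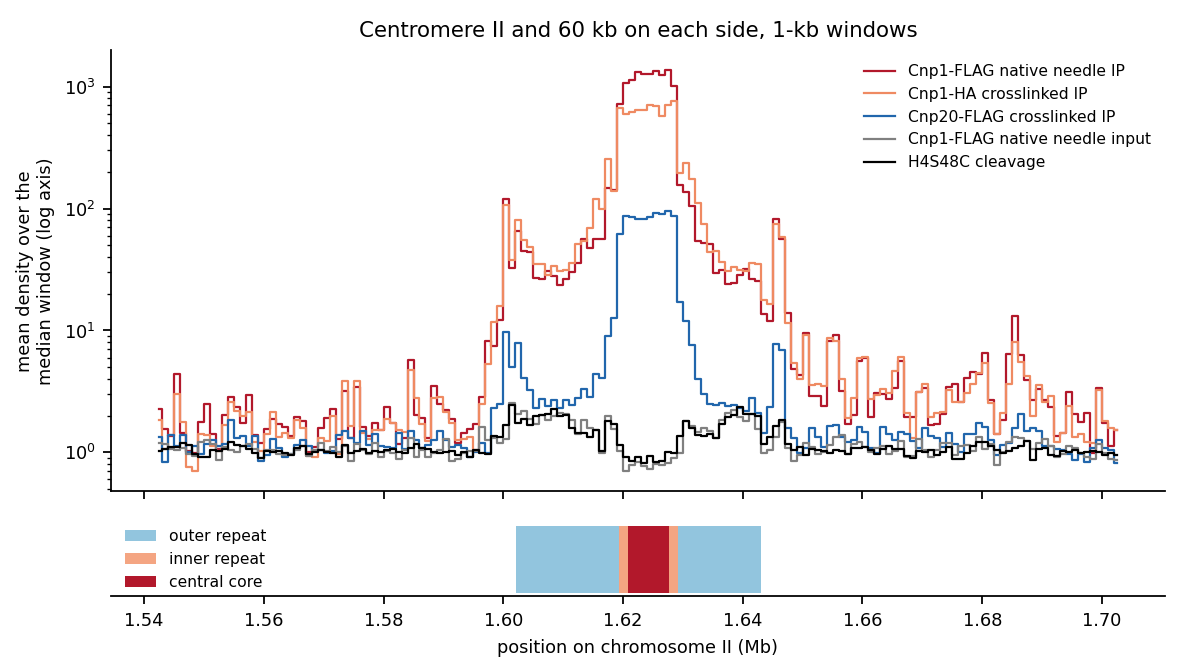
Mean density (log axis, median arm window = 1) of Cnp1-FLAG, Cnp1-HA and Cnp20 immunoprecipitates, Cnp1-FLAG inputs and H4S48C libraries in 1-kb windows along centromere II, with the central core, inner repeats and outer repeats drawn to scale below. The lines of the immunoprecipitates step down beside the inner repeats, where Cnp1-FLAG averaged 907 inside and 116 outside over all 3 centromeres.

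Fragment lengths over the cores were compared with those on the arms. In needle-extracted Cnp1-FLAG immunoprecipitates the most common length over the cores was 148 ± 1.26 bp (SD, n = 6), and in all 4 salt-extracted ones it was 147 bp. Median lengths over the cores minus those on the arms were -8.17 ± 19.0 bp in immunoprecipitates and -53.3 ± 78.6 bp in the 3 inputs (two-sided exact permutation p = 0.286, smallest possible 0.0238). The difference of 45.2 bp rested on the 1 min input, which had median lengths of 99 bp over the cores and 243 bp on the arms, and was -0.167 bp without it. H4S48C fragments were most often 140, 161 and 161 bp long over the cores and 138, 138 and 137 bp on the arms, a difference of 16.3 ± 12.4 bp (exact sign-flip permutation p = 0.25, the smallest for n = 3). The most common lengths over the cores in single libraries were 145 bp for Cnp3-Myc, 144 bp for Mis6-GFP, 132 bp for Mis6-HA, 214 bp for Scm3-FLAG, and 219 and 222 bp for native Cnp20. Minus those on the arms they were -14, -3, -16 and 65 bp, and 60 and 63 bp in native needle and salt Cnp20. By median lengths the differences were 13, -7, 78 and 10 bp, and -38 and 26 bp, so the measures did not agree. In crosslinked Cnp20 the difference by most common length was 7, 49 and -50 bp (5, 10 and 20 min).

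Within the cores, the positions of the proteins were compared through profiles of fragment midpoints. The highest Cnp1-FLAG peaks lay at 3771878 in core I (1.58 ± 0.309 of the core mean), at 1624467 in core II (1.73) and at 1101261 in core III (1.81). The inputs had 1.28 ± 0.443, 1.45 ± 0.217 and 1.56 ± 0.242 of their core mean at these positions (n = 3). H4S48C cleavage sites had 1.42 ± 0.256, 1.30 ± 0.263 and 1.34 ± 0.134 there (n = 3), and 0.840 to 1.20 at the other named peaks. The top peaks of cores I and III lie in the stretch that these centromeres share, with near equal densities (2373 and 2395). They may be 1 peak counted at both copies. At 1625047 in core II, Cnp1-FLAG had 1.64, Cnp3-Myc 2.90, Mis6-GFP 2.65 and crosslinked Cnp1-HA 2.49 times the core mean. Maxima of the Cnp1-FLAG profile numbered 25, 34 and 27 in cores I, II and III, with median spacings of 155, 190 and 160 bp. Profile correlations (Pearson's r across positions, which are not independent) had a median of 0.876 between needle-extracted Cnp1-FLAG libraries (15 pairs, 0.714 to 0.966), and of 0.234 after division by the input. With Cnp1-FLAG they were 0.708 for Cnp1-GFP, 0.352 for crosslinked Cnp1-HA, 0.308 for crosslinked Cnp20, 0.252 for Cnp3-Myc, 0.310 for Mis6-GFP and 0.0245 for Mis6-HA. With H4S48C midpoints the value was -0.159, while each H4S48C library had a median r of 0.436 to 0.444 with the others of its group. H4S48C fragments run from 1 cleavage site to the next, so their midpoints lie between the sites and do not place H4. Cnp3-Myc and Mis6-GFP, both crosslinked, had r = 0.823, and native Mis6-HA and Scm3-FLAG had 0.799. Crosslinked Cnp20 had 0.669 with Mis6-GFP but 0.231 with native Cnp20. These correlations depended on smoothing and on division by the input, under which that of Cnp1-FLAG with crosslinked Cnp1-HA was -0.0189.

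**Figure D3:**
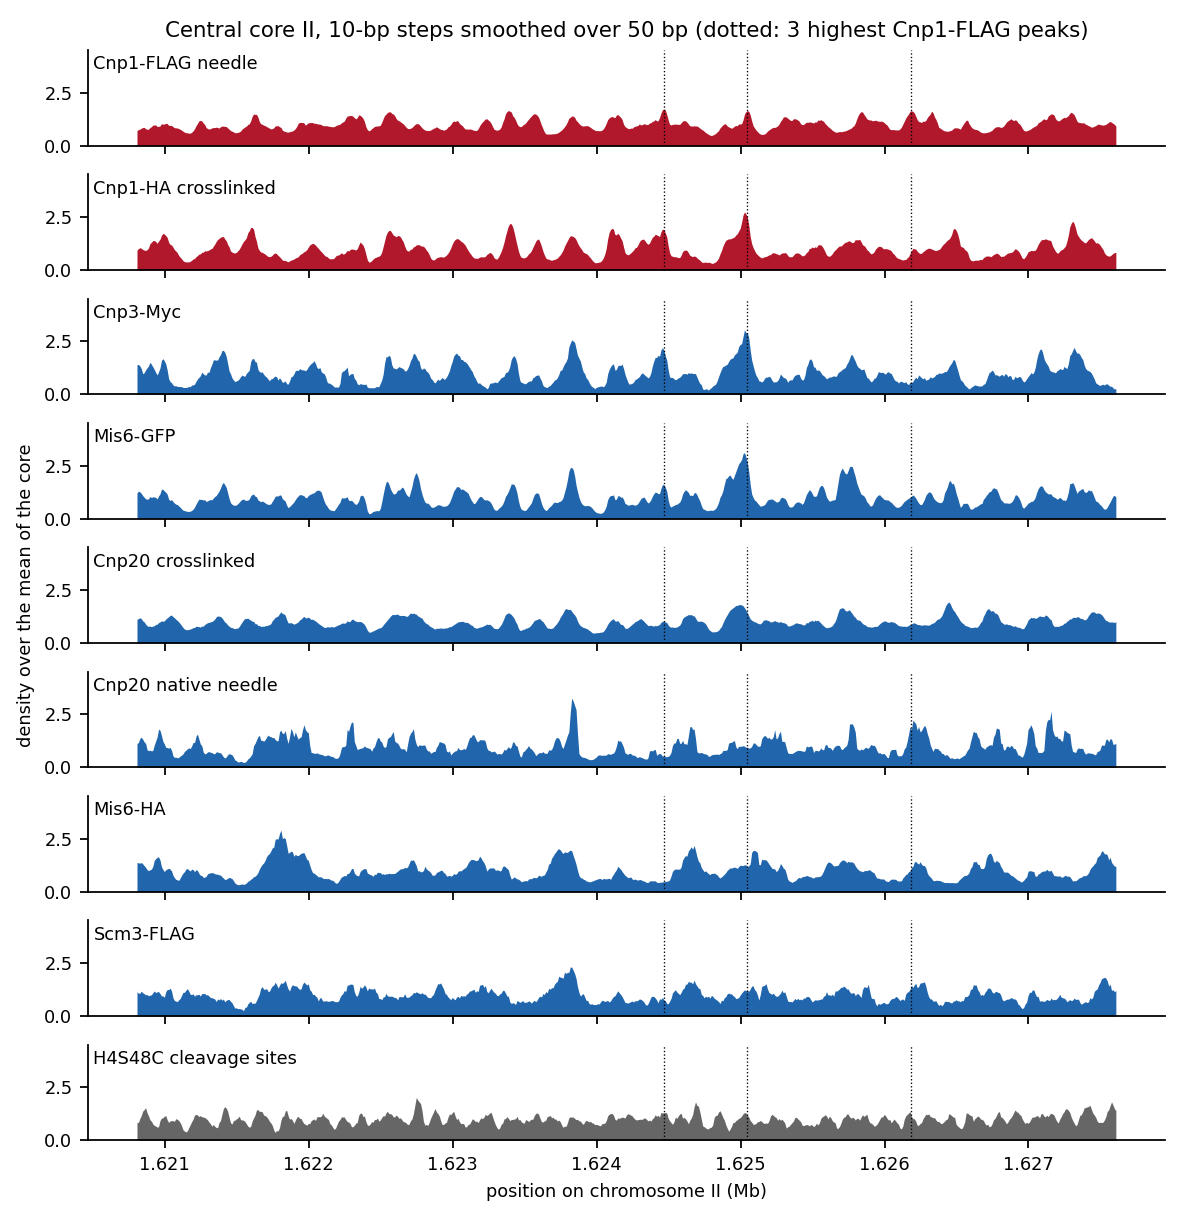
Fragment midpoints along central core II relative to the mean of the core, smoothed over 50 bp, for 8 groups of immunoprecipitates and for the cleavage sites of H4S48C libraries. Dotted lines mark the 3 highest Cnp1-FLAG peaks, at 1624467, 1625047 and 1626187.

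Away from the centromeres and the 5 kb on either side of them, Cnp1-FLAG was compared with its inputs window by window. The regions of largest mean change there were single genes or short stretches on the arms. They included ppc89 on chromosome I (3847001 to 3848000, log2 fold change 2.25, SE 0.17, limma adjusted p = 1.45e-11), crr1 on II (mean 2.22), mde6 with SPATRNACYS.03 and SPATRNAPHE.01 on I (2.20), gua1 on II (2.18) and tma19 with any2 on I (2.17). The window with the highest change in these regions lay in the stretch from ubr11 to sgo2 on I (3709001 to 3715000, 3.37, SE 0.22, adjusted p = 2.77e-13), followed by dlc2 (3.05), the stretch of prm1, lys1 and rpl1002 (3.01) and rec6 with rps402 on II (2.93). The other regions held cbs2, nse1, pcc1, sdh1 with azr1, and 2 stretches of noncoding RNA genes, with means from 1.87 to 2.05. Of 12572 windows, 488 rose and 0 fell (limma 3.58.1, adjusted p under 0.05 and a 2-fold change; 4299 had an unadjusted p under 0.05). Of these, 305 lay more than 5 kb from a centromere and 218 of them within 100 kb of one, while the other called windows lay in the centromeres or within 5 kb of them. Changes are relative to the median window: without centring, 169 rose and 12038 fell, since the median window shifted by -1.95. Over the lys1 gene the density was 2.46 ± 0.301 in immunoprecipitates and 0.997 ± 0.0417 in inputs.

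**Figure D4:**
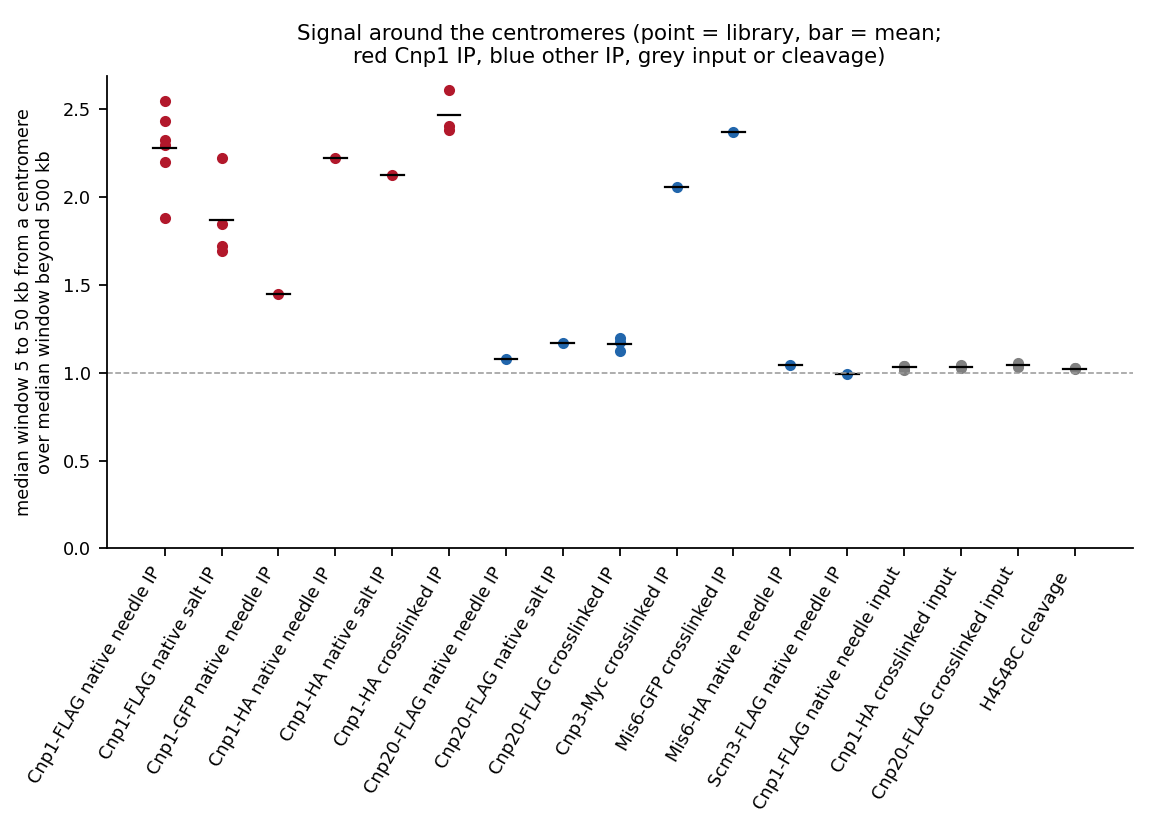
Ratio of the median window 5 to 50 kb from a centromere to the median window beyond 500 kb, with a point per library and a bar for the mean of each group of immunoprecipitates, replicated inputs or H4S48C libraries. Needle-extracted Cnp1-FLAG immunoprecipitates averaged 2.28 and their inputs 1.03.

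The arms beside the centromeres were then summarised by 1 ratio per library, a measure chosen after the data were seen. The median window at 5 to 50 kb from a centromere, a range that takes in lys1, rec6 and crr1, was 2.28 ± 0.231 times the median window beyond 500 kb in needle-extracted Cnp1-FLAG immunoprecipitates (SD, n = 6) and 1.03 ± 0.0127 times in inputs (two-sided exact permutation p = 0.0238, the smallest possible). It was 2.46 ± 0.124 in crosslinked Cnp1-HA and 1.04 in its inputs, and 1.16 ± 0.0385 in crosslinked Cnp20 and 1.04 in its inputs (exact permutation p = 0.1 for each, the smallest for n = 3). Salt-extracted Cnp1-FLAG had 1.87 ± 0.244. In single libraries it was 2.37 for Mis6-GFP and 2.06 for Cnp3-Myc, both crosslinked, 2.22 and 2.13 for native Cnp1-HA (needle and salt), 1.45 for Cnp1-GFP, 1.04 for Mis6-HA and 0.990 for Scm3-FLAG. Median log2 fold changes of Cnp1-FLAG windows were 1.20 at 5 to 25 kb, 0.92 at 25 to 50 kb, 0.57 at 50 to 100 kb, 0.23 at 100 to 200 kb and -0.07 beyond 500 kb. Across the 6 needle-extracted immunoprecipitates the ratio had r = 0.473 (permutation p = 0.328) and rho = 0.794 (permutation p = 0.0778) with MNase time, and r = 0.725 without the 2 farthest times. By mean density in fragments above 120 and up to 200 bp, native salt Cnp1-HA had 1.33 and Cnp1-GFP 0.803 (input 0.932). Fragments above 200 bp gave 1.46 and 0.817 (input 0.898), and those up to 120 bp 1.37 and 1.14 (input 0.649). Between median windows Cnp1-GFP had 1.475 above 120 and up to 200 bp (input 1.05). By medians it had 1.41 above 200 bp (input 1.02) and 1.67 up to 120 bp (input 1.04). In the class above 120 and up to 200 bp, native needle Cnp1-HA, Mis6-GFP and Cnp3-Myc had 1.94, 2.10 and 1.85.

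Gene lists set beforehand were tested in the same contrast. The tRNA genes had a median log2 fold change of 0.52, with 8 of 116 higher and 0 lower past the fold threshold, and 8 adjusted over the list alone. The 5S rRNA genes had 0.38 with 2 higher (SPRRNA.17 and SPRRNA.18), and 2 adjusted over the list alone. Ribosomal protein genes had -0.38, with 2 higher (rpl1002 and rps402) and 63 lower at any size. Highly expressed genes of glycolysis and translation had -0.42, with 15 of 23 lower at any size. With 500 bp on either side the last 2 lists had -0.089 (19 higher and 30 lower at any size) and -0.12 (6 higher and 5 lower), with camera's direction up (adjusted p = 0.760 and 0.690). Adjusted p values from camera with a preset correlation were 4.11e-09, 1.12e-05, 4.11e-09 and 0.000139 for these 4 lists, and with an estimated correlation the adjusted p = 0.425, 0.425, 0.251 and 0.425, so none held. Medians were 0.04 for Tf2 retrotransposons, 0.04 for subtelomeric genes, -0.29 for core histone genes and -0.12 for kinetochore genes, none with a member past the fold threshold and with camera adjusted p = 0.433, 0.111, 0.111 and 0.239. With distinct fragments only, Tf2 retrotransposons had 0.25 and subtelomeric genes 0.13 (camera adjusted p = 0.00934 and 0.000349, and adjusted p = 0.498 for both with an estimated correlation), and tRNA genes 0.27 with 4 higher. Meiotic genes under facultative heterochromatin had a median of -0.17 while camera's direction was up (adjusted p = 0.989), with vps29, whose place in this list was not checked against a source, as the 1 member past the fold threshold. The members named here from these counts were chosen after their values were seen.

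Crosslinked Cnp1-HA was compared with its inputs in the same way. The largest change was at ura4 and tam14 on III (115001 to 117000, mean 3.52, top window 5.57, SE 1.21, limma adjusted p = 0.000453). The 3 inputs had 4 fragments over ura4 and the 3 immunoprecipitates 205, a density ratio of 261 (95% counting interval 102 to 958), so the fitted change depends on the pseudocount. The immunoprecipitates were uneven, with ura4 densities from 0.423 to 2.83 (mean 1.35 ± 1.29, SD, n = 3) and 116 of the 205 fragments in the 5 min library, against at most 0.00453 in inputs. A window on II with SPNCRNA.1571 and SPNCRNA.1572 (3010001 to 3011000) followed at 2.74 (SE 0.16, adjusted p = 3.18e-19). Beside the centromeres, nmd5 with arp6 (2.04), gua1 (1.96), atd3 with SPCTRNAVAL.11 (1.83) and 2 long stretches on I (1.74 over 38 windows from sdh1 to srs2, 1.68 over 28 windows from bud6 to rpl1002) were higher, as were rec6 to ath1 on II (1.79), mep33, set9 and osh2. The 5 largest falls were a window of III without a gene (-1.83), mkt1 with oac1 (-1.51), bfr1 (-1.28), mei2 (-1.27) and ste24 (-1.25). In limma, 494 windows rose and 24 fell, of which 312 and 24 lay more than 5 kb from a centromere (4270 at an unadjusted p under 0.05). The 24 became 48 and 47 without the 10 min input or immunoprecipitate, 73 and 73 without the 20 min ones and 36 and 36 without the 5 min ones. Without centring, 176 rose and 11506 fell (shift of the median window -1.66). More than 5 kb from a centromere, 197 windows rose in both Cnp1 contrasts, where 7.68 would be shared by independent draws, and beyond 500 kb 0 of 8 and 48 were shared (0.0408 by independent draws).

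In the gene lists of this contrast, 5S rRNA genes had a median of 0.80 with 9 of 36 higher and 9 adjusted over the list alone. The tRNA genes had 0.63 with 20 of 113 higher and 18 adjusted over the list alone. Subtelomeric genes had 0.49 with 7 of 169 higher and 7 adjusted over the list alone. Ribosomal protein genes had -0.33 (-0.009 with 500 bp on either side), with rpl42, rpl1002 and rps402 higher and rps2502 and rpl35A02 lower, a choice made after the values were seen. Camera adjusted p values with the preset correlation were 4.42e-08, 4.42e-08, 2.77e-11 and 5.38e-05, and with an estimated correlation the adjusted p = 0.172, 0.172, 0.181 and 0.531. Core histone genes had -0.45 (adjusted p = 0.0376, and adjusted p = 0.390 with an estimated correlation), and the glycolysis and translation list -0.22 (camera adjusted p = 0.0612), but 0.16 with 500 bp on either side. Tf2 retrotransposons had 0.08, kinetochore genes -0.20 and meiotic genes -0.05, the last again with vps29 higher (camera adjusted p = 0.248, 0.248 and 0.850). With distinct fragments only, Tf2 retrotransposons had 0.43 with 13 of 13 higher at any size (camera adjusted p = 4.68e-08, and adjusted p = 0.239 with an estimated correlation), and 18 subtelomeric genes were past the threshold.

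Crosslinked Cnp20 was compared with its inputs by the same rule. The highest window held part of ste4 and sequence beside it on I (1296001 to 1297000, log2 fold change 1.77, SE 0.32, limma adjusted p = 2.16e-05), where density was 5.81 ± 3.03 in immunoprecipitates and 1.49 ± 0.105 in inputs (SD, n = 3 each). The ste4 gene as a whole had 0.13 (limma adjusted p = 0.265) and was not called. The next were lsd90 (1.26), SPAC8C9.04 (1.26), pyk1, which encodes pyruvate kinase (1.14, SE 0.10, adjusted p = 2.25e-12), bbc1 (1.12) and abp1 (1.12). Pan1, ssc1, rpl1002, pfk1, fba1, fas1, pgi1, glt1 and ssa2 followed at 1.06 to 1.01, among them the glycolytic enzymes phosphofructokinase, aldolase and glucose phosphate isomerase. The 5 largest falls were at SPBC1348.12 near an end of chromosome II (36001 to 38000, -1.51) and in windows of noncoding RNA genes near the ends of III (-1.22 and -1.14), I (-1.13) and II (-1.07). In limma, 75 windows rose and 12 fell, of which 15 and 12 lay more than 5 kb from a centromere (6626 at an unadjusted p under 0.05). Of the 15, 2 were also called higher in Cnp1-HA and 2 in Cnp1-FLAG (0.378 and 0.369 by independent draws), and 1 of the 12 falls was shared with Cnp1-HA. The pyk1 gene as a whole had 0.83 in Cnp20 and 0.72 in Cnp1-HA (limma adjusted p = 3.10e-05), with a difference of 0.11 (adjusted p = 0.751). The 15 became 27 and 27 without the 10 min input or immunoprecipitate, and the 12 became 39 and 38 without the 20 min ones and 7 and 7 without the 5 min ones. With a pseudocount of 5 CPM in place of 1, 6 rose there. Without centring, 55 rose and 144 fell (shift -0.26).

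Gene lists were tested in the Cnp20 contrast too. The tRNA genes had a median of 0.90 with 40 of 116 higher and 40 adjusted over the list alone, but -0.13 when 500 bp on either side were counted too. By time that median was 0.51, 0.75 and 1.53 (5, 10 and 20 min). It was 0.73 with fragments up to 120 bp (101 genes), 0.46 with those above 120 and up to 200 bp (106 genes, -0.023 at 5 min) and 0.23 with longer ones (13 genes). The glycolysis and translation list had 0.72, with 23 of 23 higher at any size and 0 past the fold threshold. The 5S rRNA genes had 0.61 with SPRRNA.28 past the threshold (-0.088 with 500 bp on either side), and ribosomal protein genes 0.51 with 110 of 141 higher at any size and rpl1002 past the threshold, both named after the values were seen. Tf2 retrotransposons had -0.40, with 13 of 13 lower at any size. Camera adjusted p values were 5.80e-17, 1.27e-17, 3.91e-07, 7.66e-20 and 3.56e-10 in this order, and with an estimated correlation the adjusted p = 0.489, 0.399, 0.489, 0.419 and 0.419. Subtelomeric genes had -0.05 with 1 lower past the threshold (camera adjusted p = 0.0153, and adjusted p = 0.399 with an estimated correlation). Core histone genes had 0.08, meiotic genes 0.07 and kinetochore genes 0.03, with camera's direction down for the last 2 (camera adjusted p = 0.296, 0.990 and 0.785).

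The difference between Cnp20 and Cnp1-HA was tested as an interaction of protein and immunoprecipitation, all in 1 run and without MNase time as a block. Cnp20 was higher than Cnp1-HA in the window with part of ste4 (1.99, SE 0.44, limma adjusted p = 0.00531), although the gene as a whole had 0.59 (adjusted p = 0.0395), under the fold threshold. It was also higher at bdp1 (1.64), meu7 (1.56), pho842 (1.53) and cpc2 (1.47, adjusted p = 5.11e-05), and 10 more regions from sir1 to SPAC4C5.03 had 1.44 to 1.30. It was lower at the SPNCRNA.1571 window of II (-2.27, SE 0.37), beside rpl1002 on I (-2.16), at gua1 (-2.11), at nmd5 with arp6 (-2.07) and at cbp3, tip41 and mid1 on III (-2.07). At ura4 the gene-level difference was -5.50. In limma, 139 windows were higher and 596 lower, of which 139 and 413 lay more than 5 kb from a centromere (4105 at an unadjusted p under 0.05). The 139 became 53 without the Cnp1-HA 5 min input, 341 without the Cnp1-HA 5 min immunoprecipitate, 59 and 218 without the Cnp20 10 min input and immunoprecipitate, 71 without the Cnp20 20 min immunoprecipitate and 62 without the Cnp20 5 min immunoprecipitate. Without centring, 9618 were higher and 177 lower (shift 1.39).

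Gene lists were added to this contrast after the data were seen. Glycolysis and translation genes had a median of 0.92 with 8 of 23 higher (9 adjusted over the list alone), and ribosomal protein genes 0.83 with 36 of 141 higher (37 adjusted over the list alone). With 500 bp on either side these medians fell to 0.41 and 0.24, with 0 higher in each and 3 ribosomal protein genes lower, and with distinct fragments only 3 and 28 were higher. Subtelomeric genes had -0.50 with 11 lower (12 adjusted over the list alone), Tf2 retrotransposons -0.49 and core histone genes 0.50. Camera adjusted p values were 1.05e-07, 1.65e-19, 1.01e-14, 2.33e-07 and 0.0144, and with an estimated correlation the adjusted p = 0.309, 0.295, 0.0452, 0.297 and 0.309, so that of subtelomeric genes held. The tRNA genes had 0.25 with SPATRNAARG.02 lower (-0.38 with 500 bp on either side counted), 5S rRNA genes -0.18, kinetochore genes 0.15 and meiotic genes -0.00, with vps29 lower (camera adjusted p = 0.477, 0.120, 0.477 and 0.899).

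Loci that the design named beforehand were read in all contrasts. The mating-type locus on II (2114219 to 2133394) had medians of 0.28 for Cnp1-FLAG, 0.20 for Cnp1-HA, -0.23 for Cnp20 and -0.39 for the interaction over 20 windows, with 0 called by limma. The subtelomeres of I and II had 0.17, 0.36, -0.35 and -0.64 in this order over 199 windows, with 6 higher and 1 lower in Cnp1-HA, 7 lower in Cnp20 and 18 lower in the interaction. Each of the 21 kinetochore genes lay within a 2-fold change in every contrast, including cnp3 in Cnp1-FLAG (-0.45, SE 0.10, limma adjusted p = 0.00272), cnp1 in Cnp1-HA (0.75, adjusted p = 2.15e-06) and mis18 in Cnp20 (-0.83). Among strain markers, lys1 lies 9.14 kb from centromere I and rose in Cnp1-FLAG (1.18) and Cnp1-HA (1.34, adjusted p = 9.85e-13), and ade6 had 0.18 and 0.89. The Cnp3-Myc strain carries ura4 inside the core of centromere I per its genotype, and ura4 had a density of 456 there. In Cnp1-HA inputs, whose strain carries an added Cnp1 at lys, cnp1 had 1.38 ± 0.0790 and lys1 1.31 ± 0.0767 (SD, n = 3). The cnp1 value of 0.75 in Cnp1-HA may include fragments of that added copy, which was not tested. In Cnp1-FLAG cnp1 had -0.066. In H4S48C libraries his3 had 0.105 ± 0.00259.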

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

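Of the tests in this part, those on carry-over, on the tagged protein, on crosslinked transcribed chromatin, on ura4 at its usual place and in a small share of cells, and on other splits of the libraries were chosen only after the result was seen.

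The Cnp1 signal on arms beside the centromeres covers genes such as lys1, rec6, sgo2 and gua1, with 218 of the 305 windows called in Cnp1-FLAG more than 5 kb from a centromere within 100 kb of one. Sequence shared with the centromeres is argued against, since 0.917% of those windows hold a 36-base word of a centromere, and so is chromatin left uncut by MNase, since in fragments above 120 and up to 200 bp the ratio of mean near to mean far density is 2.24 ± 0.287 (SD, n = 6) against 0.909 ± 0.0626 in inputs, though it is higher in longer ones (2.52). By mean density in the same length class, single libraries had 1.94 and 1.33 (native Cnp1-HA, needle and salt), 2.10 (Mis6-GFP) and 1.85 (Cnp3-Myc). Cnp1-GFP had 0.803 by that measure, against 0.932 in its input. Between median windows, the measure used from here on, the Cnp1-FLAG ratio in that class is 2.24 ± 0.200 against 1.03 in inputs. By this measure Cnp1-GFP had 1.475 in that class, against 1.05 in its input, so its value below the input holds for mean density only. Carry-over that follows the enrichment of the cores cannot be told apart: the only libraries of other proteins with cores as enriched as in Cnp1-FLAG, native salt Cnp20 and Mis6-HA, have ratios of at most 1.17 against 1.69 in the lowest Cnp1-FLAG library (1.88 in the lowest needle one), but they are 2 libraries from other runs. A signal that follows the tagged protein cannot be told apart either, since native Cnp1-FLAG had 2.12 and native Cnp20 1.12 with extracts averaged per run and time (exact permutation p = 0.125, the smallest for n = 7 and 1); native Cnp1-HA had 2.22 and 2.13, but Cnp1-GFP had 1.45, and crosslinked Mis6-GFP (2.37) and Cnp3-Myc (2.06) show the ratio without Cnp1 as the tagged protein.

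Crosslinked Cnp20 differed from crosslinked Cnp1-HA in the test of the difference, with 139 windows higher (at bdp1, cpc2 and others) and 596 lower, and subtelomeric genes had a median difference of -0.50. In crosslinked Cnp20 the glycolysis and translation list had a median of 0.72, with 0 of 23 genes past the fold threshold in limma, 23 of 23 higher at any size, and a camera adjusted p = 0.399 with an estimated correlation. Fragment lengths as the cause of that median are argued against, since it is 0.77 with fragments above 120 and up to 200 bp. Crosslinked transcribed chromatin that enters any immunoprecipitate stays open: the list had -0.22 in crosslinked Cnp1-HA, but 0.037 in its 5 min libraries alone and 0.16 with 500 bp on either side of the genes. Whether Cnp20 sits at these genes without crosslinking stays open too, since the list lies at percentile 95.3 of 10000 random lists in the native salt library and at 100 in the needle one, while the ribosomal protein list lies at 100 in both, 2 extracts of 1 run and time, and contact of Cnp20 with transcribed chromatin is a candidate explanation only.

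Fragments of ura4 in crosslinked Cnp1-HA immunoprecipitates numbered 205, of which 116 in the 5 min library, against 4 in the inputs, where the gene is all but missing. Cells with ura4 at its usual place are argued against, since the inputs would then hold 1044 fragments at the density of the immunoprecipitates. Copies of fragments sequenced for Cnp3-Myc, whose strain has ura4 in a core, are argued against too: 0.976% of the fragments share both ends with that library, against 11.9% of the 1064 ura4 fragments of crosslinked Cnp20. A small share of cells with ura4 inside a core may be present, but the ratio of immunoprecipitates to inputs of 261 (102 to 958, counting error only) is too wide to tell, beside 803 at the cores, and densities in the 3 immunoprecipitates run from 0.423 to 2.83. Chromatin carried over from the Cnp3-Myc culture was not tested.

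The contig MTR, which the comparisons leave out, had a density of 2.51 ± 0.476 in needle-extracted Cnp1-FLAG immunoprecipitates (SD, n = 6) against 0.384 ± 0.0295 in inputs, and 3.13 ± 0.355 in crosslinked Cnp1-HA against 0.333 ± 0.0252 (n = 3 each). It was 0.412 ± 0.0684 in crosslinked Cnp20 against 0.399 ± 0.0151 in inputs, and 0.869 in Cnp1-GFP against 1.01 in its input. Single libraries without an input had 4.64 and 7.52 (native Cnp1-HA), 1.77 (Cnp3-Myc), 1.51 (Mis6-GFP), 0.413 (Mis6-HA) and 0.345 (Scm3-FLAG). In Cnp1-FLAG the signal lay at 9001 to 14000, highest at 12001 to 13000 (16.8 ± 4.06 against 0.994 in inputs). Its sequence is not in the reference used, so no gene is named there. In the needle-extracted and salt-extracted Cnp1-FLAG immunoprecipitates, the only groups large enough to test, 0 of 30 tests for a single distant value among measures such as core density found one, where chance would give 1.5.

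Other splits of the same libraries were fitted with limma. For Cnp1-FLAG, 1 of 84 splits, the real one, gave 488 called windows and the highest of the others 0. This share is under 0.05 and argues against chance only for libraries that can be exchanged freely. Every other split mixes immunoprecipitates with inputs, so few calls were likely there. The inputs share a run with 3 of the 6 immunoprecipitates, and within that run the splits are too few for a share under 0.05. For Cnp1-HA (518 windows), Cnp20 (87) and the interaction (735), 1 of 10 splits, the real one, gave as many and the highest of the others 0 in each, and 10 splits are too few for a share under 0.05.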

How the results depend on the processing

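Chosen only after the data were seen were scaling to a trimmed mean, limma without a trend, leaving out ribosomal DNA, distinct fragments or length classes for border, near-centromere and gene list values, H4S48C ends, averages of native extracts per run and time, and gene lists in the interaction.

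Regions named by the rule kept direction and side of the threshold in 212 of 225 repeats under an alternative (11 lost the call at a pseudocount of 5 CPM and 2 with distinct fragments). Single values did so in 81 of 91, gene lists in 74 of 117, and profile correlations stayed within the spread in 117 of 217. Where no cause is given below, the cause was not tested.

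Core density of Cnp1-FLAG over inputs was 782-fold in 1 run (exact p = 0.1, the smallest with fewer libraries, as by construction), and 921 to 1241 leaving out 1 library each, where leaving out an input raises the smallest exact p to 0.0714 by construction. The salt to needle ratio was 2.02 with distinct fragments (exact p = 0.0159) and 0.965 with fragments up to 120 bp (exact p = 0.921), and 1.12 to 1.501 leaving out 1 library each. Leaving out 1 library, Cnp1-HA cores ranged from 718 to 866, Cnp20 cores from 62.8 to 113, the ratio of inner repeats to cores from 0.794 to 0.825, the Cnp1-FLAG length difference from -0.167 (without the 1 min input) to 69.8 bp and that of H4S48C from 12.5 to 23.5 bp.

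Without centring, which counts the shift of the median window as change, windows rose in 169 cases for Cnp1-FLAG and 176 for Cnp1-HA, and 9795 differed in the interaction. With windows of 500 bp the counts were 975, 1111, 189 (Cnp20) and 1779. Leaving out 1 library gave 472 to 538, 489 to 547, 65 to 94 and 548 to 1079.

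With distinct fragments, Tf2 retrotransposons in Cnp1-FLAG (0.25) and Cnp1-HA (0.43) and subtelomeric genes in Cnp1-FLAG (0.13) came past the camera threshold, and subtelomeric genes in Cnp20 (-0.02) fell under it. Gene lists past the camera threshold fell to 2 for Cnp1-FLAG and 3 for Cnp1-HA with 500 bp on either side, and to 0, 0 and 0 with an estimated correlation. With the flanks, ribosomal protein medians came to -0.089 in Cnp1-FLAG, -0.009 in Cnp1-HA and 0.24 in the interaction, and medians reversed for tRNA genes (-0.13 in Cnp20, -0.38 in the interaction) and 5S rRNA genes in Cnp20 (-0.088). Medians of lists under the threshold both ways reversed too: Tf2 (-0.092 in Cnp1-FLAG, -0.033 in Cnp1-HA), glycolysis and translation (0.16) and meiotic genes (0.037) in Cnp1-HA, and kinetochore genes in Cnp20 (-0.021).

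The Cnp1-FLAG profile correlation was 0.234 after division by the input. Reversed after division were those of needle-extracted Cnp1-FLAG with Cnp1-HA (-0.0189) and Cnp20 (-0.0223), of salt-extracted Cnp1-FLAG with them (-0.0224 and -0.0562) and of Cnp1-GFP with Cnp20 (-0.0210). Reversed over 150 bp were salt-extracted Cnp1-FLAG with Cnp1-HA (-0.0341) and Cnp3-Myc (-0.0207), and native Cnp1-HA with Mis6-HA (-0.0501).

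Depth limits arm windows in salt-extracted chromatin, where the median window held 9 fragments in the shallowest Cnp1-FLAG library and in the Cnp1-HA one.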

Other observations

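Beyond the outer repeats of centromere II, pairs of windows with tRNA genes carried high Cnp1 signal. The window at 1600001 to 1601000, with SPBTRNAILE.05 and SPBTRNAALA.08, had 119 ± 58.2 in needle-extracted Cnp1-FLAG (SD, n = 6), 107 ± 18.7 in crosslinked Cnp1-HA and 9.80 ± 2.53 in crosslinked Cnp20 (n = 3 each), against 1.30 ± 0.159 in Cnp1-FLAG inputs and 1.68 ± 0.127 in H4S48C libraries. On the other side, the window at 1645001 to 1646000, with SPBTRNALYS.08, SPBTRNAILE.08 and SPBTRNAALA.11, had 82.4 ± 39.8, 75.2 ± 19.6 and 7.75 ± 1.76 against 1.34 ± 0.127 in inputs. Both windows were singled out after their values were seen, and whether sequence shared with the border tRNA genes contributes was not tested.

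The ste4 window, highest in crosslinked Cnp20, had 12.4 in native salt-extracted Cnp20 and 3.24 in native needle-extracted Cnp20, against 1.20 ± 0.127 in crosslinked Cnp1-HA and 1.14 ± 0.152 in needle-extracted Cnp1-FLAG immunoprecipitates. The native Cnp20 values are single libraries, count repeated fragments and may rest on few molecules. Over ura4, distinct fragments numbered 5 of 115 in that salt library and 128 of 837 in the needle one. The ade6 gene had 10.2 in the Cnp1-FLAG 1 min immunoprecipitate and 5.75 in its input, while the lowest of the 6 immunoprecipitates had 1.45. The mis6 gene had 2.47 in Mis6-GFP and 3.26 in Mis6-HA, the libraries in which Mis6 carries the tag. The cnp20 gene had 1.72 ± 0.121 in crosslinked Cnp20 immunoprecipitates and 1.24 ± 0.151 in their inputs (n = 3 each). In the native needle library of Cnp1-HA, sequenced in the same run as Cnp3-Myc, 20 of 43 ura4 fragments shared both ends with a Cnp3-Myc fragment. The native salt library of that run had 8 of 10. High shares were also seen in other runs, with 11 of 19 in salt-extracted Cnp1-FLAG 10 min immunoprecipitate replicate 1 and 40 of 115 in native salt-extracted Cnp20. Ribosomal DNA took 25.8% of the Cnp1-GFP immunoprecipitate. The profile of salt-extracted Cnp1-FLAG 10 min immunoprecipitate replicate 1 had a median r of 0.49 with the other salt libraries and 0.72 with native salt-extracted Cnp1-HA, across positions.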
